A study of Drosophila melanogaster with 3 samples.

How the data were processed

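Peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) (antibody against GFP per the description in the labels, while the antibody label gives CG6765) were analysed for 3 biological replicates of Drosophila melanogaster embryos carrying CG6765 fused to eGFP. The labels put all samples in 1 group and number the replicates 1 to 3. They also name a possible control experiment, which is not analysed here. Per the labels, chromatin was sonicated to a size range of 200 to 800 bp.

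The authors deposited, on the assemblies dm6 and dm3, a candidate peak list for each replicate, a candidate list called on the pooled replicates, and a list thresholded for reproducibility that was derived from the replicate and pooled lists, per the labels in the descriptions deposited with each sample. Per the same descriptions the signal was called against a control. The aligner, the peak caller, their versions and the threshold are not given in the sources used here. In each list the authors give per peak a signal value, of no stated unit, a q-value as its −log10, and the position of the summit. The −log10 q-value of thresholded peaks on dm6, as deposited, reached at most 3.67, a value shared by 61.3% of them, so it was not used to rank peaks. The authors' signal values are not comparable between lists and were used only to order peaks within a list. All candidate lists held 30000 regions, so their ranks can be set side by side. Most intervals have a fixed width (456 bp in 97.6% of pooled candidates), so the width was not read as a measurement. The thresholded peaks were tested to be exactly the 3816 pooled candidates of highest signal on dm6, and the 3034 of highest signal on dm3.

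Positions were taken from the dm6 lists, whose peaks all end within the arms of the reference used here, and are given counting from 1. Gene models came from Ensembl release 115 for assembly BDGP6.54, which has the same coordinates. No position was converted between assemblies, and the dm3 lists were used only for counts and chromosome shares. Analyses covered arms 2L, 2R, 3L, 3R, 4 and X, with 13945 protein-coding genes. Read numbers are not in the lists, so depth is unknown and intervals cover only the counting of peaks or genes.

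Peaks of the pooled candidate list that were not thresholded served as the comparison, leaving out 1101 that overlapped a thresholded peak, which left 25083. The candidate lists are labelled as peaks and background, so this comparison set includes background regions. Summits within 100 bp were counted as shared. Replicate overlap was the share of the 3816 strongest summits shared by a pair of replicates, averaged over both directions, and was compared with 1000 circular shifts of one list along each arm. A summit was assigned to the first of 7 classes that held it: promoter (within 500 bp of any annotated start site), 5' UTR, 3' UTR, coding exon, non-coding exon, intron and intergenic. A gene was counted as having a peak if a thresholded summit lay within 500 bp of any of its start sites. Motifs were searched as consensus words on both strands within 50 bp of the summit. Words of 8 bases found in at least 20 peaks were ranked on 2L, 2R and 4 and the first was tested on 3L, 3R and X.

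Shares were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 7 classes, 6 arms, 29 gene lists or 28 motifs and a threshold of 0.05. Shares carry Wilson 95% intervals, and odds ratios carry 95% intervals on the log scale. Shares of classes, gene lists, motifs and chromosome X were also computed in the replicates' own lists. There the 3816 strongest peaks were set against the remaining ones, or used alone for the gene lists. Where such shares are given as mean ± SD, n = 3. With 3 replicates an exact sign-flip test cannot go below p = 0.25. The relation of signal to promoter class was tested with 100000 permutations. The gene lists, the motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Afterwards 13 older gene symbols in the lists were mapped to the symbols of the annotation, after a first count of the lists had been seen, and pcl and Dpt did not match and were left out. The rule named CG6765 first, then the gene nearest to each of the 25 thresholded peaks of highest signal, then, for each list that differed, the 3 members with the strongest peak (all members with a peak where the list had fewer than expected), and last any of the 25 strongest peaks of a replicate that no thresholded peak covered, of which there were 0.

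The alternatives were the 1908 strongest thresholded peaks, other summit distances (50 and 200 bp) or interval overlap, other numbers of peaks per replicate (1000 and 7632), other distances to start sites (250, 1000 and 2000 bp), only the 3816 candidates ranked directly below the threshold, the replicates' own lists, leaving out each replicate, other motif distances (25 and 100 bp), comparison peaks matched on GC content and promoter class (1 planned draw, and 100 draws added after the data had been seen because the single draw was unstable), genes matched on number of start sites and length (10000 random lists), only genes with a candidate peak, assignment to the nearest start site, the dm3 lists, and words of 6 and 10 bases. The word leading most often in these draws, the support by signal in the full lists, the BTB list without CG6765, and the housekeeping list without RpLP0 and without RpLP0, sta and Fer2LCH were also added after the data had been seen. When a replicate was left out, the promoter and chromosome X values were the geometric mean of the odds ratios of the other replicates.

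The statistics were tested on simulated data with known answers. With 13945 genes, the list test recovered a planted odds ratio of 4 in 100 of 100 simulations for the ribosomal protein list and in 49 of 100 for the housekeeping list, and called 0.01 unplanted lists per data set. A word planted in 2% or 5% of 1908 peaks ranked first in 10 of 10 simulations, and a planted overlap of 25% was estimated as 25.4%. Genes outside the planted lists all had the same probability of a peak, and both sets of sequences came from the same candidates. The simulations therefore do not show the error rate where start sites, gene length or GC content differ. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.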

Results

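The series profiled where CG6765, tagged at its C terminus with enhanced green fluorescent protein (eGFP), was recovered on chromatin of whole Drosophila melanogaster embryos collected between 0 and 24 h of development from cultures of mixed sex. Chromatin was sheared by sonication to fragments of 200 to 800 bp and immunoprecipitated, and the DNA was sequenced (ChIP-seq). The description in the labels gives an antibody against GFP and the antibody label gives CG6765, so the antibody is taken here from the description. The labels give 1 group of 3 biological replicates and no comparison group among the samples, and the comparisons made here set the peaks that passed the authors' reproducibility threshold against weaker candidate peaks, the replicates against each other, and named gene groups against other genes. On the dm6 assembly the authors' thresholded list held 3816 peaks with a median width of 456 bp, which together covered 1534 kb or 1.15% of the 6 major chromosome arms. The candidate lists of replicates 1, 2 and 3 and of the pooled replicates each held 30000 regions. They are labelled as peaks and background, given as input to the reproducibility step. The median −log10 q-value was 0.605 among all pooled candidates, while thresholded peaks had at least 2.70. Many of the weaker candidate peaks may therefore be background and not weak binding sites. The signal value of a peak is the authors' own and was used only to rank peaks within a list; among thresholded peaks it ran from 135 to 2699 with a median of 193. The number of reads behind each replicate is unknown from these lists, so every interval below covers the counting of peaks or genes only, and peaks and genes are not biological replicates.

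CG6765 (FBgn0035903; 3L, 8512767 to 8518738, plus strand) carried a thresholded peak at its own start site. This peak spanned 8512467 to 8512677 on 3L in dm6, had its summit at 8512574, 193 bp from the nearest annotated start of CG6765 and within the neighbouring gene Pus7, and ranked 501 of the pooled candidates with a signal of 391. A summit within 100 bp of it ranked 558, 1394 and 135 in the lists of replicates 1, 2 and 3. The 51 bp around that summit read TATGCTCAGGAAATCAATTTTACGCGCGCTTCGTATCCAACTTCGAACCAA. A pair of further thresholded peaks lay inside CG6765, at summit 8513491 in an intron (rank 2959) and at summit 8514807 next to the start site of the nested gene CG6683 (rank 3160). In replicates 1, 2 and 3, summits within 100 bp ranked 1571, 9010 and 2776 for the former and 11302, 4847 and 1661 for the latter. Candidate summits were dense along this neighbourhood, with 17 pooled candidates within 10 kb of the middle of the gene against a median of 5 for other protein-coding genes.

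**Figure D1:**
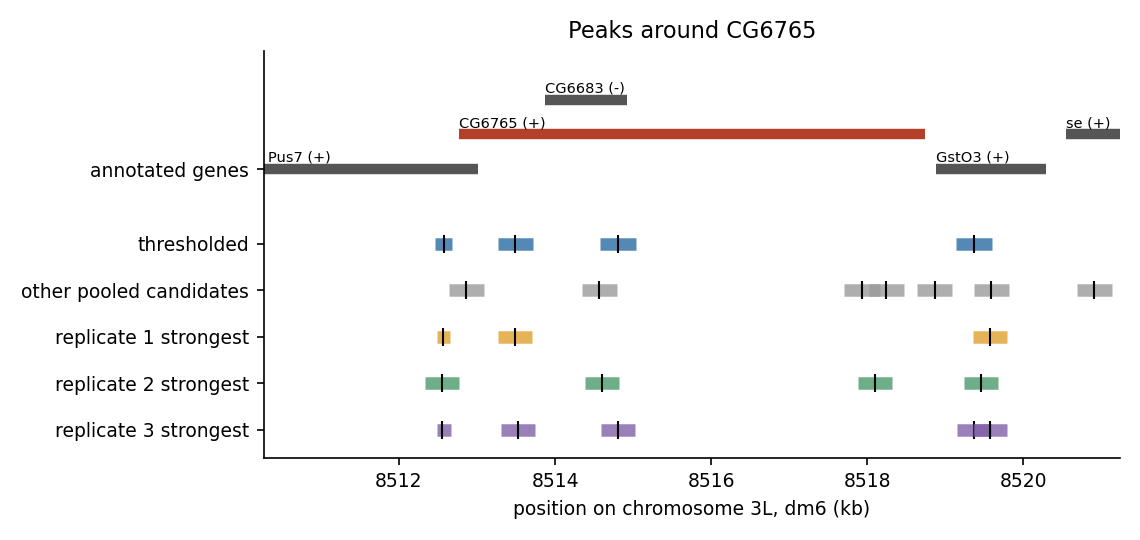
Map of the CG6765 neighbourhood on chromosome 3L (dm6, position in kb), with annotated genes and their strand on top, then thresholded peaks, the other pooled candidates, and the 3816 strongest peaks of each replicate; bars are peak intervals and ticks are summits. Among these strongest peaks, all 3 replicates hold a summit at the start of CG6765, near 8512574. The thresholded peaks inside the gene are held by some replicates only at this cut, and by all 3 in the full lists.

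The strongest peaks were at CG11050, Ugalt, Hsp83, jp and Trl, and most of the 25 strongest were at start sites. The highest signal, 2699, was at an intron of CG11050 (2L, 6612410 to 6612960, summit 1037 bp from a start site), and this region ranked 1, 1 and 2 in replicates 1, 2 and 3. The next were the promoter of Ugalt, which encodes a UDP-galactose transporter (X, 2703691 to 2704082, signal 2218), and the promoter of Hsp83, the fly Hsp90 chaperone (3L, 3192897 to 3193292, signal 1962). They were followed by an intergenic site 761 bp from jp (2L, 9567315 to 9567714, signal 1942) and an intron of Trl, which encodes GAGA factor (3L, 14759300 to 14759741, signal 1852). Around the CG11050 summit the 51 bp read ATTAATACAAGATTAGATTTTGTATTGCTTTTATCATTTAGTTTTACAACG, with a GC content of 21.6%, around the Ugalt summit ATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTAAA, with 25.5%, and around the Trl summit GC content was 31.4%. The Hsp83 and jp summits had a GC content of 49.0% and 54.9%. Of the 25 strongest peaks 17 had their summit within 500 bp of an annotated start site. Besides Ugalt and Hsp83 these were nearest to CG14100, Gapdh2, mRpL41, px, CG13390, CenG1A, Alg3, RpS27, CG1635, RpL7, Fkbp14, shn, lncRNA:CR31840, mRpS10 and CG18549. The others lay farther out, nearest to lncRNA:CR44619 (in an exon of lncRNA:Vinr), cbt (in an intron of ush), Lk6 (intron), CG32772 (intron) and sbb (intron, 20098 bp from the closest start site), in addition to CG11050, jp and Trl. Of these 25 peaks 24 ranked 100 or better in all 3 replicates; the exception, at Alg3, ranked 102, 11 and 9. Every one of the 25 strongest peaks of each replicate had a thresholded summit within 100 bp.

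The strongest peaks recurred between replicates far more often than shifted lists. Of the 3816 highest-ranked summits of one replicate, 53.3% ± 1.79 (SD over 3 pairs) lay within 100 bp of one of the 3816 highest-ranked summits of another. The pairs gave 54.3% for replicates 1 and 2, 51.3% for 1 and 3, and 54.4% for 2 and 3. Shifting one list along the arms gave a mean of 0.570% to 0.580%, and the highest of 1000 shifts reached 2.94%. The one-sided circular-shift permutation test gave p = 0.001 for each pair, the smallest that 1000 shifts can give, and 0.001 after Benjamini-Hochberg adjustment over the 3 pairs. Shifts also move summits away from promoters and other candidate regions. The test therefore shows only more overlap than random placement along the arms would give. Among thresholded peaks, 1536 (40.3%, Wilson 95% interval 38.7 to 41.8) were held by the 3816 strongest of all 3 replicates, 1312 (34.4%) by 2, 858 (22.5%) by 1 and 110 (2.88%) by none. In the full candidate lists, 91.4% ± 2.54 (SD, n = 3) of thresholded peaks had a summit within 100 bp, and 77.3% had one in all 3 replicates. That last share was 93.4% among the 954 thresholded peaks of highest signal and 63.3% among the 954 of lowest signal, where the pooled signal was itself made from these replicates. Among the 3816 strongest of each replicate the contrast was larger, with 91.1% of the 954 of highest signal held by all 3, 54.2% and 15.4% of the following groups of 954, and 0.314% of the 954 of lowest signal. Peaks of lowest pooled signal rank close to this cut, so the larger contrast follows at least in part from the cut.

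Thresholded peaks were concentrated at start sites of genes. Their summits lay within 500 bp of an annotated start site in 56.7% of cases (2164 of 3816, interval 55.1 to 58.3), against 26.4% (6624 of 25083) of the other candidate peaks, while such positions make up 13.6% of the arms. In the replicates' own lists the share was 56.5% ± 1.82 among the 3816 strongest peaks and 26.6% ± 2.68 among the remaining ones (SD, n = 3), higher among the strongest in 3 of 3. The odds ratio was 3.65 (95% interval 3.40 to 3.91; two-sided Fisher's exact test across peaks, p = 9.1e-290, adjusted 6.4e-289 over 7 classes). Introns held 31.8% of thresholded and 45.4% of other candidate summits, regions between genes 8.65% and 18.7%, 3' UTRs 0.943% and 2.75%, and coding exons 0.262% (10 summits) and 4.80%. Each was lower among thresholded peaks by Fisher's exact test (adjusted p = 1.0e-56, 1.6e-59, 1.8e-13 and 6.0e-60) and in 3 of 3 replicates. The 5' UTR share (0.760% against 1.10%, adjusted p = 0.0707) and the non-coding exon share (0.839% against 0.921%, adjusted p = 0.714) did not pass the same exact test. An exact sign-flip test on 3 replicates cannot give less than p = 0.25, which is what the promoter share gave. Against only the 3816 candidates ranked directly below the threshold, 44.7% of which were at promoters, the odds ratio was 1.62 (exact p = 1.4e-25).

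**Figure D2:**
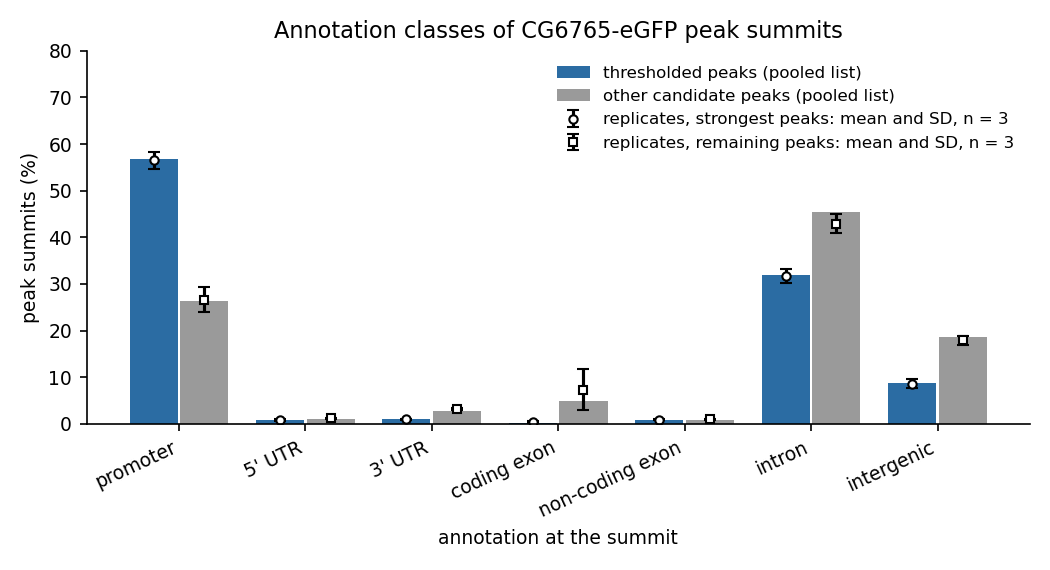
Share of peak summits (%) in each annotation class, for the 3816 thresholded peaks and the 25083 other candidate peaks of the pooled list (bars), with the mean and SD of the 3 replicates' own strongest and remaining peaks (symbols). Promoters hold 56.7% of thresholded and 26.4% of other summits, and introns, coding exons and intergenic regions hold smaller shares of the thresholded ones.

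Within the thresholded peaks, those of higher signal were slightly more often at promoters. The promoter share was 62.8% among the 954 of highest signal, 54.9% and 58.0% in the following groups of 954, and 51.2% among the 954 of lowest signal. Spearman's rho between signal and promoter class was 0.0828 across the 3816 pooled peaks and 0.108, 0.0850 and 0.0892 in the strongest peaks of replicates 1, 2 and 3. Each of these 4 relations gave p = 1e-05 in a two-sided permutation test across peaks, the smallest that 100000 permutations can give, and 1e-05 after adjustment.

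**Figure D3:**
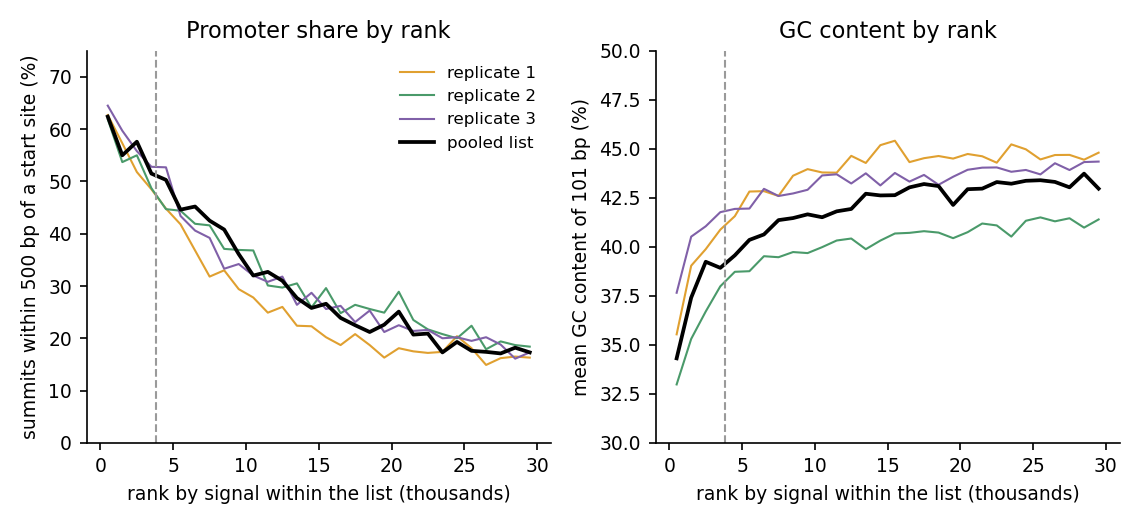
Promoter share (%, left) and mean GC content within 50 bp of the summit (%, right) in successive groups of 1000 candidate peaks ordered by signal within each list (x axis, rank), for the pooled list and each of the 3 replicates; the dashed line marks 3816 peaks. In the pooled list the promoter share goes from 62.4% in the first 1000 to 17.3% in the last 1000, and GC content from 34.3% to 43.0%.

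Chromosome X held 15.3% of thresholded summits (585 of 3816), and 4009 of the 25083 other candidate summits lay there. This difference did not pass the test (odds ratio 0.952, interval 0.866 to 1.05, two-sided Fisher's exact test across peaks, p = 0.318), and the X share of the strongest peaks was above that of the remaining ones in replicate 1 (16.9% against 16.4%) and below it in replicates 2 (15.85% against 15.91%) and 3 (14.7% against 15.2%). The odds ratio was 1.04 for the 1908 strongest thresholded peaks (exact p = 0.582) and 0.871 against the next 3816 candidates only (exact p = 0.0277). Among the other arms, 2R held 20.4% of thresholded and 18.3% of other summits (odds ratio 1.15, exact test, adjusted p = 0.00969 over 6 arms), and shares on 2L, 3L, 3R and 4 did not pass. Shares on these other arms were not compared in the replicates' own lists. Chromosome 4 had 15.6 thresholded peaks per Mb against 30.8 on 2R. Other candidates were sparse there too, and it held 0.550% of thresholded and 0.347% of other summits (odds ratio 1.59, interval 0.986 to 2.56, exact test, adjusted p = 0.190).

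Genes for cytoplasmic ribosomal proteins stood out most among the 29 gene lists. A thresholded summit lay within 500 bp of a start site in 76 of 92 of them (82.6%, interval 73.6 to 89.0), against 16.6% of other protein-coding genes, and in 78.6% ± 5.14 of them in the strongest peaks of the 3 replicates (SD, n = 3). The odds ratio was 23.9 (two-sided Fisher's exact test across genes, adjusted p = 6.1e-42 over the lists). The members of highest signal were RpS27 (3R, 25247345 to 25247693, summit on a start site, signal 1233; the start sites of Nup37 and sisRNA:CR46364 were also within 500 bp), RpL7 (2L, 10200880 to 10201191, signal 1195; Ripalpha also within 500 bp) and RpL14 (3L, 8600801 to 8601143, signal 944; Nelf-E and snoRNA:U49:66Da also within 500 bp). Abundant housekeeping genes had a peak in 14 of 20 (70.0%, interval 48.1 to 85.5), and 73.3% ± 2.89 of them in the replicates (SD, n = 3). The odds ratio was 11.5 (exact test, adjusted p = 1.6e-06). The members of highest signal were Gapdh2 (X, 15867784 to 15868171, signal 1510) and Eno (2L, 1727805 to 1728081, signal 643), both glycolytic enzymes, and the ribosomal protein gene RpLP0 (3L, 22075931 to 22076214, signal 752). Another member with a peak, sta, also encodes a ribosomal protein, and Fer1HCH and Fer2LCH, the ferritin genes, shared 1 peak that was counted for both, so that the 14 genes stood for 13 separate peaks. Without RpLP0, sta and Fer2LCH, an alternative chosen after seeing the data, 11 of 17 had a peak (odds ratio 8.99, exact test, adjusted p = 0.000110). Both lists also passed when only genes with any candidate peak were compared and when set against random lists matched on start sites and gene length, where 17.4 ribosomal protein genes and 6.18 housekeeping genes with a peak were expected.

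Genes of a group fixed as BTB zinc finger genes had a peak in 9 of 22 (40.9%, interval 23.3 to 61.3; 39.4% ± 6.94 in the replicates; odds ratio 3.39, exact test, adjusted p = 0.0403). The members of highest signal within 500 bp of a start site were lola (2R, 10541758 to 10542213, signal 415), rdx (3R, 13983400 to 13983855, signal 399) and CG6765 itself. The other members with a peak were Trl, whose stronger intron peak (signal 1852) lay farther out, CG12236, psq, ken, rib and Kr-h1. Some of these, such as rdx, psq and Kr-h1, do not combine both domains that the list is named for. This call did not hold without CG6765 (8 of 21, exact test, adjusted p = 0.0719, chosen after seeing the data), for the 1908 strongest peaks (0.209) or within 250 bp (0.0891). Nor did it hold among genes with a candidate peak (exact test, adjusted p = 0.594). The list passed within 1000 bp, within 2000 bp and by nearest start site (exact tests, adjusted p = 0.00817, 0.000456 and 3.7e-08). Against permutation lists matched on start sites and gene length, 7.01 members with a peak were expected (adjusted p = 0.792).

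Insulator and architectural protein genes (7 of 16, odds ratio 3.81, adjusted p = 0.0540), Polycomb and Trithorax group genes (10 of 27, odds ratio 2.88, adjusted p = 0.0690) and heat-shock genes (7 of 20, adjusted p = 0.171) did not pass the exact test. The first and second of these lists passed within 250 bp and within 1000 bp. The first also passed for the 1908 strongest peaks, where the second gave an adjusted p of 0.565 by the exact test. Within 2000 bp each of these lists passed, with an odds ratio of 3.15 for heat-shock genes (exact test, adjusted p = 0.0387). Against permutation lists matched on start sites and gene length, 3.30 and 6.67 members with a peak were expected in the first and second list (adjusted p = 0.260 and 0.479). Among genes with a candidate peak the exact test gave the first and second list adjusted p = 0.594 and 0.561. Members with strong promoter peaks, named after their values were seen, were Chro (signal 1062), Dref (819) and Cp190 (649) in the first list, and ph-p (984), brm (666) and E(z) (538) in the second. The peak counted for Dref is also the one counted for the ribosomal protein gene RpL13. Single members of other lists that did not pass, picked in the same way, also had strong peaks. Among them were elav (828), fkh (708) and trh (573), so strong single peaks were not particular to the first and second list. Tracheal genes had a peak in 4 of 10 and did not pass within 500 bp (exact test, adjusted p = 0.179). Only by nearest start site did they pass (odds ratio 6.56, adjusted p = 0.0161 by the exact test). Within 500 bp, genes that pattern the embryo did not pass either. A peak was found at Hox genes in 0 of 8, gap and terminal genes 2 of 13, pair-rule genes 2 of 11, segment polarity genes 4 of 15, dorsoventral genes 2 of 19, neuroblast and neurogenesis genes 3 of 20, and Notch pathway and E(spl) genes 4 of 19, with exact tests giving adjusted p from 0.522 to 1. Nor did muscle differentiation genes (6 of 23), midgut and endoderm genes (2 of 9), haemocyte and fat body genes (1 of 17) or germ-cell genes (1 of 12) pass. The same held for ecdysone-response genes (4 of 16), cell-cycle genes (7 of 28), circadian genes (2 of 10), immune effector genes (1 of 18) and proteasome subunit genes (5 of 31, 16.1%, exact test, adjusted p = 1). In lists of this size the test recovered a 4-fold odds ratio in 49 of 100 simulations with 20 genes, so differences of that size or smaller were often not detectable.

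Fewer peaks than at other genes were found at odorant and gustatory receptor genes, 1 of 120 (0.833%, interval 0.147 to 4.57; 0.278% ± 0.481 in the replicates; odds ratio 0.0406, exact test, adjusted p = 1.0e-07). The exception, Gr97a, had its summit (3R, 26966723 to 26967178, signal 153) 466 bp from its start site and within CG5521, whose own start site was also within 500 bp. Replication-dependent histone genes had none in 111 (upper limit 3.35%, exact test, adjusted p = 2.8e-08), but none of them had any candidate peak either, and these repeated, near-identical copies share reads, so their value is uncertain. When only genes with a candidate peak were compared, 14 receptor genes remained and that call did not hold (exact test, adjusted p = 0.413). No peak within 500 bp was found at Osiris genes (0 of 23) or yolk and chorion genes (0 of 16). The same held for larval glue and cuticle genes (0 of 18) and testis-specific genes (0 of 18). These 4 lists did not pass the exact test within 500 bp (exact test, adjusted p = 0.0850, 0.205, 0.167 and 0.167). All 4 passed the exact test within 2000 bp. In permutation lists matched on start sites and gene length, 3.26, 1.53, 1.61 and 2.43 members with a peak were expected. None of the 4 passed this permutation test (permutation test, adjusted p = 0.260, 0.724, 0.724 and 0.379). Only 4, 1, 5 and 1 members had any candidate peak, and none of the lists passed the exact test among such genes.

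**Figure D4:**
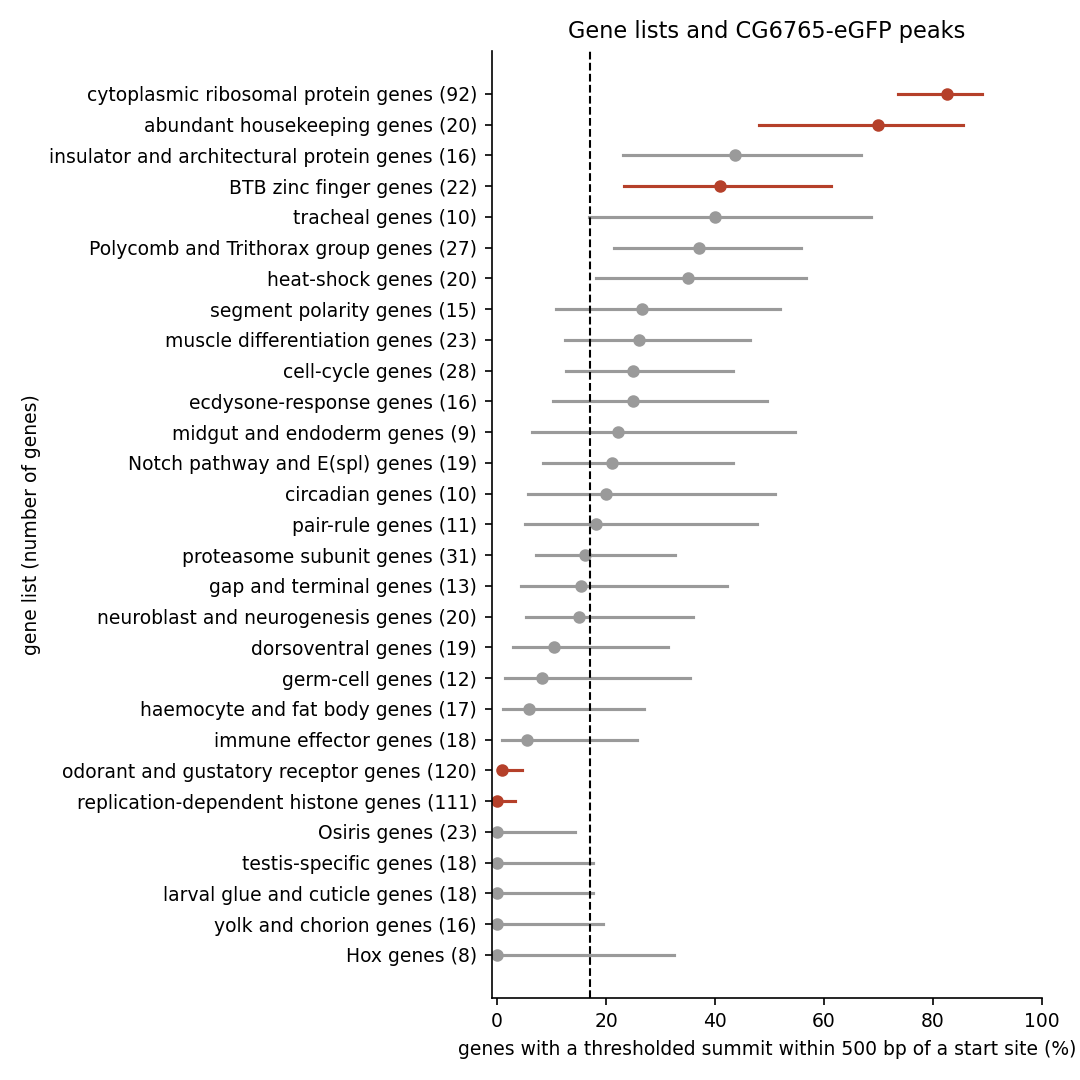
Share of genes (%) with a thresholded summit within 500 bp of an annotated start site in each of the 29 gene lists (points) with Wilson 95% intervals (lines); the number of genes is in brackets, the dashed line is the share of all protein-coding genes, 17.0%, and red marks lists with an adjusted p under 0.05. Ribosomal protein genes (82.6%) and abundant housekeeping genes (70.0%) lie far above the line and the receptor and histone genes below it.

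The sequence at thresholded summits was rich in A and T. Mean GC content within 50 bp of the summit was 37.4% among thresholded and 42.4% among other candidate peaks, and 38.2% ± 2.28 against 42.7% ± 1.99 in the replicates' strongest and remaining peaks (SD, n = 3), lower among the strongest in 3 of 3. Of 28 sequence motifs, 12 differed in two-sided Fisher's exact tests across peaks with adjustment over the motifs. The exact test found 8 more often. By exact tests they were the TATA box (12.6% against 8.30%, odds ratio 1.59, adjusted p = 4.2e-15), the homeodomain site (8.33% against 6.04%, adjusted p = 2.6e-06), core promoter motifs 7 (5.14% against 3.48%, adjusted p = 6.9e-06) and 6 (3.56% against 2.47%, adjusted p = 0.000513), and the DREF element (1.39% against 0.606%, odds ratio 2.31, adjusted p = 6.9e-06). The same exact test passed for the CTCF core (0.943% against 0.419%, adjusted p = 0.000285), the M1BP element (0.760% against 0.407%, adjusted p = 0.0118) and the BEAF-32 core (14.5% against 12.9%, adjusted p = 0.0137). The Tramtrack site, which is bound by a BTB zinc finger protein, was found less often (0.0786%, 3 summits, against 0.606%, odds ratio 0.129, exact test, adjusted p = 6.9e-06), as were the CA repeat (2.28% against 3.66%), the runt site (1.76% against 2.41%) and the GC box (2.67% against 4.20%). The GAGA factor repeat (2.31% against 1.77%, adjusted p = 0.0600) and the Zelda site (0.393% against 0.431%, adjusted p = 0.967) did not pass the exact test. Within 100 bp of the summit the GAGA factor repeat passed (odds ratio 1.67, exact test, adjusted p = 8.3e-11). Against the next 3816 candidates 4 motifs passed, and when every replicate's own peaks had to pass 7 did. The former included the Grainyhead site (odds ratio 0.0831, exact test, adjusted p = 0.0317) and the latter the inverted CAAT box (odds ratio 0.879, exact tests, adjusted p = 0.0341). Neither was among the 12 (adjusted p = 0.108 and 0.319 by exact tests). The CTCF core was in neither group, with an odds ratio of 1.03 against the next candidates (exact test, adjusted p = 1) and an adjusted p of 0.685 by the exact test for the largest p of the replicates. Core promoter motif 7 was in neither group (adjusted p = 0.411 and 0.0557 by the same exact tests). With 3420 comparison peaks matched on GC content and promoter class, Fisher's exact test passed for 0 of the 28 motifs in the draw planned beforehand (5 at an unadjusted p under 0.05), which depended on the draw. In 100 further draws, chosen after seeing the data, 0 to 5 motifs passed, with at least 1 in 89 draws. The CTCF core passed in 70 of them (median odds ratio 2.95), core promoter motif 7 in 48 and the GAGA factor repeat in 24, each with an odds ratio above 1 in all 100. The A tract passed in 35 and the Tramtrack site in 25. Both were less frequent at thresholded summits in all 100 draws (median odds ratios 0.783 and 0.223). Without matching the A tract had an odds ratio of 1.08 (exact test, adjusted p = 0.373). The TATA box, the homeodomain site and core promoter motif 6 passed in 0 of them, with median odds ratios of 0.933, 0.942 and 0.982. The GC box, less frequent without matching, also passed in 0, with a median of 1.03 and a value above 1 in 71 draws. The DREF element, the M1BP element and the BEAF-32 core likewise passed in 0, with medians of 1.22, 1.18 and 1.04.

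The 8-base word that best separated thresholded from other candidate peaks on 2L, 2R and 4 was TATTTTAA. On 3L, 3R and X, where it had not been chosen, it was within 50 bp of the summit in 4.63% of thresholded (107 of 2311) and 1.76% of other candidate peaks (276 of 15702), an odds ratio of 2.71 (interval 2.16 to 3.41, two-sided Fisher's exact test across peaks, p = 1.8e-15). The 10 leading words all passed on those chromosomes and included TTTAAAAA (5.28% against 2.55%) and TTCTTAAA. With matched comparison peaks the word TATTTTAA had an odds ratio of 1.46 (median of the 100 draws, 1.19 to 1.83) and a p under 0.05 by the exact test in 79 draws. A search repeated on matched peaks found ATGCTTAA in the planned draw (odds ratio 0.800, exact p = 0.596) and 39 different words in the 100 draws, with a median odds ratio of 1.09. The word found most often, CGGAAACG, led in 17 draws and passed the exact test on 3L, 3R and X in each of these 17. Across all 100 draws, which share the same thresholded peaks, its median odds ratio was 4.03 (1.86 to 20.2), with an unadjusted p under 0.05 in 98. Without matching it was found in 0.952% of thresholded (22 of 2311) and 0.395% of other candidate peaks on those chromosomes (odds ratio 2.42, interval 1.49 to 3.95, exact p = 0.000840). This word was tested only after the draws had been seen.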

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

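The list alternatives without CG6765, without RpLP0 (13 of 19 housekeeping genes with a peak) or without RpLP0, sta and Fer2LCH (11 of 17) and the 100 matched draws, with the word they gave most often, were chosen after seeing the data. The replicate values moved with the number of peaks compared and with the definition of a shared peak. The mean overlap between replicates, 53.3%, became 40.3% with summits within 50 bp, 61.1% within 200 bp, 62.0% with intervals overlapping by at least 50% of the shorter one, 66.6% with the 1000 strongest peaks and 46.0% with 7632. Leaving out each replicate gave 51.3% to 54.4%, by construction the values of the single pairs that remain. The share of thresholded peaks held by all replicates, 40.3%, became 27.5%, 48.5%, 50.1%, 14.9% and 61.6% under the same settings, where 1000 peaks can hold only about 26.2% of 3816 by construction, 72.6% for the 1908 strongest thresholded peaks, and 49.0% to 53.3% when each replicate was left out, which asks for fewer replicates by construction. The peak set counted 1908 peaks by the stricter choice, by construction, and 3034 on dm3. The promoter odds ratio of 3.65 kept its direction and passed in every alternative, between 1.62 and 3.99. The chromosome X odds ratio turned to 1.04 (exact p = 0.582) for the 1908 strongest peaks and ran from 0.980 to 1.02 as each replicate was left out, none of which passed, and became 0.871 (exact p = 0.0277) against the next 3816 candidates; the cause was not tested. Of 29 gene lists, 5 passed; 12 did within 2000 bp, 9 by nearest start site and 2 among genes with a candidate peak, where fewer genes are tested. The 5 lists lost their call in 6 of 37 alternative values and never turned direction; 5 of the losses were the BTB list. The ecdysone-response list turned to 0.652 of its expected count when matched (permutation, adjusted p = 0.724), having passed only by nearest start site. Of 28 motifs 12 passed, against 4 with the next 3816 candidates, 7 when all 3 replicates had to pass (each with 1 motif not among the 12, the Grainyhead site and the inverted CAAT box) and 0 with comparison peaks matched on GC content and promoter class, where there are fewer comparison peaks. That 0 came from 1 random draw: 100 draws gave a median of 2 and a range of 0 to 5. Against the next 3816 candidates the odds ratio turned to 0.767 for the GAGA repeat, 0.949 for the BEAF-32 core, 0.935 for the M1BP element and 0.992 for core promoter motif 6; with matched peaks it turned to 0.899 for motif 6, 0.886 for the TATA box and 0.989 for the homeodomain site. A word search repeated on matched peaks gave ATGCTTAA in the planned draw, with an odds ratio of 0.800 (exact p = 0.596). Over 100 draws the first words, nearly all other than TATTTTAA, had a median of 1.09. Among them, CGGAAACG had a median of 4.03 when tested in all 100 draws. TATTTTAA, the leading word without matching, had a median of 1.46 (1.19 to 1.83) and an exact p under 0.05 in 79 draws. None of these causes was tested beyond that. Lists and motifs that passed in no planned setting (15 and 13) are not given singly, and 22 and 24 of their values went the other way. The unknown depth limits all of these values.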

Other observations

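Several genes carried many separate thresholded summits along their bodies. The most were at sbb, with 12 (2R, 18278198 to 18357296; 11.3 ± 2.08 in the replicates' strongest peaks, SD, n = 3), followed by shn with 11 (2R, 11159086 to 11217394; 11.0 ± 1.00) and CHES-1-like with 11 over 27.0 kb (X, 7682338 to 7709385; 11.7 ± 1.53). The genes ush, bun and lncRNA:CR44357 had 10 each, dnc, Eip75B, CG1677 and rdx 9 each, and ftz-f1, crp, tara, RapGAP1, Svil and Tlk 8 each, where CG1677 lies within lncRNA:CR44357, so that its summits are counted for both. Longer genes can hold more summits, and these counts were not tested against gene length. Among the genes named, summits per 100 kb ran from 4.18 at lncRNA:CR44357 (239 kb) to 40.7 at CHES-1-like. Of 13945 protein-coding genes, 1652 held at least 1 thresholded summit in the body, 62 at least 5 and 15 at least 8. Among genes that are not protein-coding, a thresholded summit lay within 500 bp of a start site in 24 of 290 tRNA genes (8.28%), 22 of 269 snoRNA genes (8.18%), 196 of 3261 ncRNA genes (6.01%) and 3 of 268 pseudogenes (1.12%), against 17.0% of protein-coding genes. The counts were 1 of 32 for snRNA genes and 0 of 99 for rRNA genes, and these differences were not tested.

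Matching on gene length and start sites was planned, but the bound its result is read against here was set after that result had been seen. Both tests of the CG6765 locus were chosen after the results they bear on had been seen, and the second locus test replaced the first after the first had given its result. No biological explanation was tested, since the samples form 1 group.

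Ribosomal protein genes had a peak in 82.6% of cases. If the promoters of genes transcribed in nearly all cells were recovered alike, whatever the tagged protein does, nuclear genes for the respiratory chain and ATP synthase should show a similar share, but 14.3% of them did (12 of 84, interval 8.37 to 23.3), below the ribosomal protein interval (73.6 to 89.0); mitochondrial ribosomal protein genes (16 of 73, 21.9%) and tRNA synthetase genes (4 of 17, 23.5%) did not pass a test against other genes either (exact tests, adjusted p = 0.661 for each list). The respiratory chain list was taken by the start of gene symbols. Members not transcribed in nearly all cells were not removed, and any such members could lower its share. Number of start sites and gene length do not account for the ribosomal protein share either, since the count was 4.36 times that of matched lists. An effect of the highest transcription rates alone stays open, because no expression values and no profile of an unrelated tagged protein were used here, and the share of 70.0% at abundant housekeeping genes is in line with it. A role of CG6765 at these promoters may be considered only as a hypothesis.

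Thresholded summits were richer in A and T than other candidate summits by a GC gap of -4.98 percentage points (bootstrap 95% interval -5.38 to -4.60 over 131 blocks of 1 Mb). A bias of the libraries towards AT-rich fragments would reach over the fragment length if it acted evenly on whole fragments. The gap in the flanks 150 to 250 bp away was 9.14% of that at the summit (interval 3.79 to 14.4, 10.2% ± 19.9 in the replicates, n = 3). This share was 21.0%, -12.8% and 22.4% in replicates 1, 2 and 3. The libraries also differed in base composition, with a GC content at the remaining summits of 44.2%, 40.4% and 43.5% in that order. A small flank gap cannot exclude a bias that centres summits on short AT-rich stretches, so library bias stays open. A larger share of promoters does not account for the gap at the summit, since the gap within classes was 103% of the plain gap (bootstrap interval reaching up to 105%, 93.9% ± 11.0 in the replicates, n = 3). Mean GC content was 38.5% against 43.5% at promoters, 35.6% against 41.0% in introns and 36.2% against 41.4% between genes, which counts against a property of promoter DNA as the whole cause. A candidate explanation that stays open, and was not tested, is a preference for short AT-rich stretches, whether of the tagged protein or of the recovery of open DNA in general.

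Around CG6765 there were 17 pooled candidate summits within 10 kb of the middle of the gene, a number reached around only 146 of 13944 other protein-coding genes, and the tagged strain carries an insertion whose extra copies could add reads over a whole stretch of DNA. The first test counted summits outside promoters, with a percentile under 95 set to count against extra copies, and it gave 68.4 in the pooled list (68.4 to 89.7 over all lists), under that bound. It is not taken to exclude them, because coding exons, weighed only afterwards, held 4 summits in each of replicates 1 and 3 (percentiles 97.8 and 98.9), though 1 in the pooled list and 0 in replicate 2. After the first result the test was also changed to summits per kb outside promoters, since promoters fill 43.1% of this window against a median of 25.9%, with the bound against extra copies moved to 50, and the percentile was 83.4 in the pooled list and 90.4, 83.4 and 96.9 in replicates 1, 2 and 3, against 98.8, 89.6, 96.4 and 96.7 inside promoters. The values outside promoters lie between the bounds, and the excess that extra copies would give is unknown, so extra copies and binding at these promoters cannot be told apart.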
